A study of Mus musculus with 8 samples.

How the data were processed

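The deposited matrices held raw counts of unique molecular identifiers (UMIs) for every barcode, before any call of cells, with 1 matrix per library. They were made with the 10x Chromium 3′ v3.1 Dual Index chemistry and counted by Cell Ranger 7.1.0 against mouse build mm10. The annotation release and the aligner settings are not given in the sources used here. Each matrix listed 32287 features, among them the reporters eYFP and tdTomato, and 78 symbols occurred more than once and were kept apart by Ensembl identifier.

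The groups, the tests, the gene lists, the cell type markers, the rule for naming genes and most of the alternative settings were fixed before the data were examined. Alternatives added after seeing the data were the red pulp macrophage fit without its low-UMI cluster, other scalings and no filter for the Cd163 fits, and other totals or groupings for the class shares. All results on the reporters were also chosen after seeing the data.

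A barcode was called a cell with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored per library with Scrublet, and the highest scores were removed at 0.8% per 1000 called cells, which took 1.96% to 6.22% of cells. Cells of the 4 libraries of a fraction were clustered together with scanpy 1.11.5, using 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, without batch integration. Cd163 and the haemoglobin, immunoglobulin, sex-linked, mitochondrial and ribosomal genes were left out of the variable genes. A cluster took the name of the marker list, out of 21, whose mean was at least 1 log2 unit above the other cells and at least 1 above the next best list, with at least 3 markers detected in at least 20% of its cells. Other clusters kept a number. A cluster that met these criteria also kept a number where it was of low depth and its leading genes lacked the list's markers. In such a cluster the median UMIs were below those of its libraries by a factor of more than 3. None of the list's markers were among its 10 top genes. Such clusters were CD64-positive cluster 24 and CD45-negative clusters 12 and 15. Cluster 24 met the criteria of the marginal zone/metallophilic list, whose marker Marco came just after its 10 top genes. CD45-negative clusters 2, 17 and 25 failed these criteria but met the erythroid rule given below, and kept a number for the same reason. A cluster whose 10 top genes had more markers of another list kept a number too. This held for CD64-positive cluster 14, which met these criteria, and for CD45-negative cluster 27, which met only the erythroid rule. By the erythroid rule, a CD45-negative cluster that failed the criteria was named erythroid with at least 4 erythroid markers other than haemoglobin at 50 CPM or more. Erythroid clusters of that fraction were divided by haemoglobin level. The names end in "-like" because they rest on RNA alone.

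UMIs were summed per library and class, and a class was fitted when each of its 4 libraries held at least 20 cells. This left 12 classes in each fraction. Infected and control sums were compared with the edgeR 4.0.16 quasi-likelihood (QL) test (robust, TMM scaling, filterByExpr, two-sided), and a gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05. DESeq2 1.42.0 was the second tool. The number in the sample titles does not pair a control with an infected animal, so no pairing entered these fits. Standard errors (SE) are those of the log2 fold change. UMIs scaled to library size (CPM) are given as the mean with the standard deviation (SD) of 2 mice per group, and n is 2 mice per group unless stated. An exact permutation test of 2 against 2 mice cannot give a two-sided p below 0.333, and the shares of cells with a UMI were compared without a test.

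Of 24 fixed gene lists, those with at least 3 tested members were tested per class with camera (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation, and fry, with BH adjustment over the lists of a class. Of 542 pairs of list and class, camera called 148 with the preset correlation and 0 with an estimated correlation, while fry called 6. A gene counted as passing "over the list alone" had a p adjusted over the list's tested members.

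Genes were named by 3 rules. The first took up to 10 higher and 10 lower called genes with the largest fold change, a mean log2 CPM of at least 5 and both infected libraries on the same side of both controls. The second took up to 4 members of each list with the smallest p. The third always took Cd163, Spic, Vcam1, Hmox1, Slc40a1, Siglec1, Cd5l, Fcgr1 and Ptprc. Any other gene named is said to have been chosen after its values were seen.

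For shares of cells with a UMI of one gene, each cell was thinned at random to 5000 UMIs, cells below that depth were left out, and 95% intervals are exact Clopper-Pearson. Intervals and limits cover counting error only. The Cd163 comparison within red pulp macrophage-like cells set cells with at least 1 Cd163 UMI after thinning against cells with none, as 2 sums per mouse with the mouse as a block. Class shares were tested with the edgeR QL test on cell counts, with all called cells of the library as the total, and BH adjustment within a fraction.

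Counts were simulated with the depth of the real sums and, for every gene, the spread of the trend at its level. Real genes can spread more than that trend, and recovery may be lower for them. In these counts the red pulp macrophage fit recovered 75% of genes changed by 1 log2 unit and 95% of those changed by 2. Of its 186 calls 16 (8.60%) were false. The marginal zone fit recovered 85% and 96%, and the endothelial fit 79% and 98%. The Cd163 fit recovered 59% and 99%, and its interaction with infection 11% and 49%. Reads from near-identical genes, such as Rnaset2a and Rnaset2b, H2-Q6 and H2-Q7, or Hspa1a and Hspa1b, cannot be assigned with certainty. Gene positions are from GENCODE vM21 on mm10.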

Results

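Single-cell RNA was measured in spleens of 5 to 6 month old mice that had received either the blood-stage malaria parasite Plasmodium chabaudi, 90 days before, or saline. The series asks whether Cd163, a haemoglobin-haptoglobin scavenger receptor, marks a subset of red pulp macrophages and how these cells relate to the marginal metallophilic macrophages of the same organ. Red pulp macrophages clear old red blood cells and recycle iron, and metallophilic and marginal zone macrophages line the border of the white pulp. The mice carried a Cre reporter (eYFP) for the Tnfrsf11a lineage and a Flp reporter (tdTomato) for descendants of Ms4a3-expressing progenitors, the precursors of granulocytes and monocytes. A magnetically enriched CD45-negative fraction and a sorted CD64-positive fraction were each sequenced from 2 control and 2 infected mice, giving 8 libraries. The sample titles number the mice 2 and 99 in both groups, and these numbers are used here, but the library names give the infected mice other numbers. Titles and library names use the same label for a mouse in both fractions, so the fractions of a number are taken to come from the same mouse, and no test joined them. The library names read CD65pos where the titles give CD64-positive, and the titles were followed. The labels give no day or batch of sorting or library preparation, so a batch that follows the infected and control groups is not excluded for any value that compares them. CD64 is the Fc receptor encoded by Fcgr1, and CD45 is encoded by Ptprc.

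The CD45-negative libraries held 133452622 and 93267067 UMIs in control mice 2 and 99, and 105827042 and 129453129 in infected mice 2 and 99. The CD64-positive libraries held 43114793 and 49615801 in controls and 59240969 and 65999939 in infected mice. Called cells carried 85.2% to 89.9% of these UMIs in the CD45-negative fraction and 54.7% to 62.5% in the CD64-positive fraction. The numbers of CD45-negative cells were 7292 and 2732 in controls and 3673 and 5790 in infected mice, with medians of 12587.5, 15655.5, 19303 and 13741.5 UMIs per cell. The numbers of CD64-positive cells were 2407 and 2466 in controls and 3591 and 4357 in infected mice, with medians of 6542, 7231.5, 6869 and 5905 UMIs.

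The CD64-positive fraction held red pulp macrophage-like and marginal zone/metallophilic macrophage-like cells beside monocyte-like, dendritic cell-like and many B and T cell-like cells. Marginal zone/metallophilic macrophage-like cells, with Timd4, Marco and Siglec1 among their RNAs, made up 8.64% and 10.1% of the cells of control mice and 3.73% and 3.37% of those of infected mice. The fall, a log2 fold change of −1.40 (SE 0.34, adjusted p = 0.00088, edgeR QL test over 23 classes), was no longer called without infected mouse 2 (adjusted p = 0.129) or infected mouse 99 (0.493). T cell-like cells rose from 10.3% and 17.2% to 36.1% and 35.6% (log2 fold change 1.38, SE 0.26, adjusted p = 2.6e-05), a call lost without infected mouse 2 (0.0528) or infected mouse 99 (0.167). Fibroblast-like cells, log2 fold change −1.36 (SE 0.26, adjusted p = 2.6e-05), and cluster 24, a low-UMI group led by Ccl24 and Ubd (−2.44, SE 0.41, adjusted p = 6.4e-06), fell as well. Cluster 24 met the marker criteria of the marginal zone/metallophilic list and kept a number by the rule for clusters of low depth. The call for cluster 24 was lost without control mouse 99 (adjusted p = 0.214). Red pulp macrophage-like cells made up 8.18% and 10.8% of control and 8.05% and 7.44% of infected cells (adjusted p = 0.480). Of the red pulp plus marginal zone/metallophilic macrophage-like cells, the red pulp class made up 48.6% (exact 95% interval 43.7% to 53.6%) and 51.6% (47.1% to 55.9%) in controls and 68.3% (63.7% to 72.7%) and 68.8% (64.4% to 73.0%) in infected mice. With all lymphoid classes left out of the total, a choice made after seeing the data, the log2 fold change of the marginal zone/metallophilic class was −0.90 (SE 0.37, adjusted p = 0.0826) and that of the red pulp class 0.20 (adjusted p = 0.599). All classes share 1 total, so the rise of T cell-like cells by itself lowers the other shares, those of fibroblast-like cells and cluster 24 included. Shares in a sorted fraction depend on the sort as well as on the tissue.

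In the CD45-negative fraction, clusters 5 and 8 fell from 8.78% and 9.48% to 2.56% and 3.13% (log2 fold change −1.68, SE 0.27, adjusted p = 2.3e-06) and from 7.91% and 9.15% to 2.50% and 2.63% (−1.73, SE 0.25, adjusted p = 7.4e-07, edgeR QL test over 19 classes). Cluster 5 was led by Ass1, Apoe and Muc13, and cluster 8 by Angpt1 and Scin, with Meis1, a transcription factor of blood stem and progenitor cells. Both calls passed with each library left out. Cluster 12, led by the chemokines Ccl4, Ccl6 and Ccl3 and the histamine-forming enzyme Hdc, fell (−0.97, SE 0.27, adjusted p = 0.00508), and cluster 2, with a median of 1401 UMIs, rose (1.83, SE 0.44, adjusted p = 0.00508). Without control mouse 2, control mouse 99 or infected mouse 99, cluster 12 had an adjusted p of 0.439, 0.100 and 0.0892 and cluster 2 one of 0.302, 0.154 and 0.0736.

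**Figure D1:**
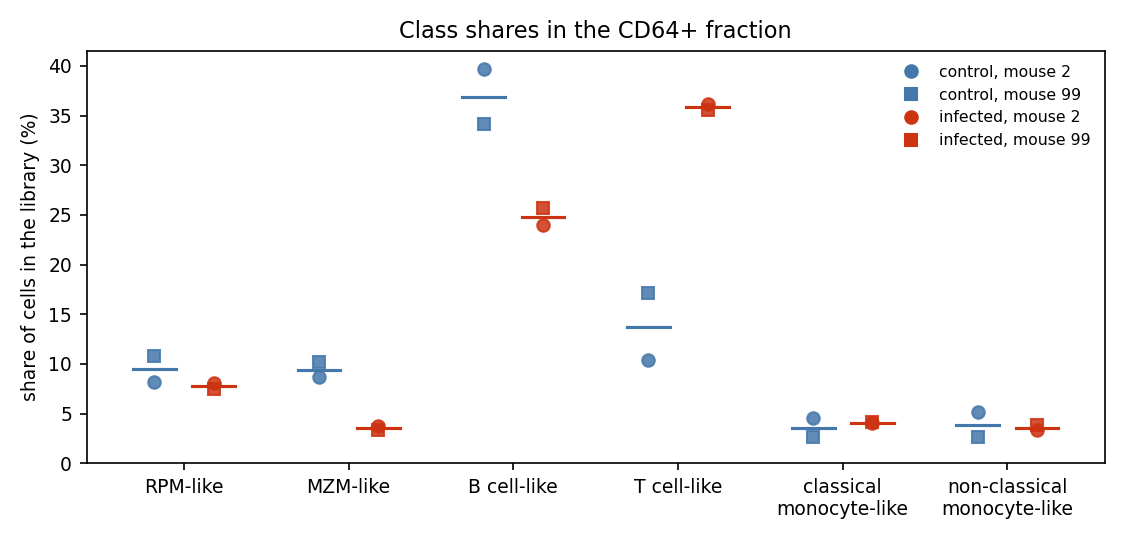
Percent of called cells in 6 classes of the CD64-positive fraction, per library, with lines at the means of 2 mice (RPM-like, red pulp macrophage-like; MZM-like, marginal zone/metallophilic macrophage-like). MZM-like cells lay at 8.64% and 10.1% in controls and at 3.73% and 3.37% in infected mice.

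Cd163 RNA in red pulp macrophage-like cells was low in both infected mice. Cd163 (chromosome 6, 124304656 to 124330527, plus strand, mm10) was at 126 and 261 CPM in control mice 2 and 99 and at 27.0 and 35.2 CPM in infected mice 2 and 99. The means were 194 ± 95 and 31.1 ± 5.86 (mean ± SD, n = 2). After thinning, 31.0% (exact 95% interval 23.6% to 39.2%) and 48.2% (41.4% to 55.0%) of control red pulp macrophage-like cells held a Cd163 UMI, against 9.68% (6.30% to 14.1%) and 9.19% (6.04% to 13.3%) in infected mice. The group means were 39.6% ± 12.1 and 9.43% ± 0.344 (SD, n = 2), with 52, 46, 41 and 52 cells below the thinning depth left out. T cell-like cells, which should lack Cd163, had shares of 1.0%, 0.775%, 0% (0 of 938 cells, which allows up to 0.320%) and 0.346%. The median depth of the cells kept was 6360.5, 6463, 6751 and 6299 UMIs, against 12676, 15926, 14450 and 13160 in red pulp macrophage-like cells. Marginal zone/metallophilic macrophage-like cells had 0% in all 4 libraries, which allows up to 1.47%, 1.22%, 2.27% and 2.07%. Without thinning the red pulp shares were 35.5%, 51.1%, 19.0% and 21.3%, and marginal zone/metallophilic macrophage-like cells had 0.80% in control mouse 99, 1.49% in infected mouse 2 and 0% in the other mice.

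The log2 fold change of Cd163 was −2.67 (SE 0.50), which did not pass over all genes (edgeR QL test, adjusted p = 0.325). DESeq2 gave −2.63 with an adjusted p of 0.000965, and the edgeR fit with the replicate block gave −2.59 with an adjusted p of 4.3e-07, although the replicate numbers do not pair the mice. Fits that leave out a control mouse drop the spread between the control mice from the error, so passing there adds no support. Without control mouse 2 the edgeR log2 fold change was −3.06 and without control mouse 99 it was −2.03. Without infected mouse 2 it was −2.47 (adjusted p = 0.0988) and without infected mouse 99 −2.86 (0.161), and neither passed.

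**Figure D2:**
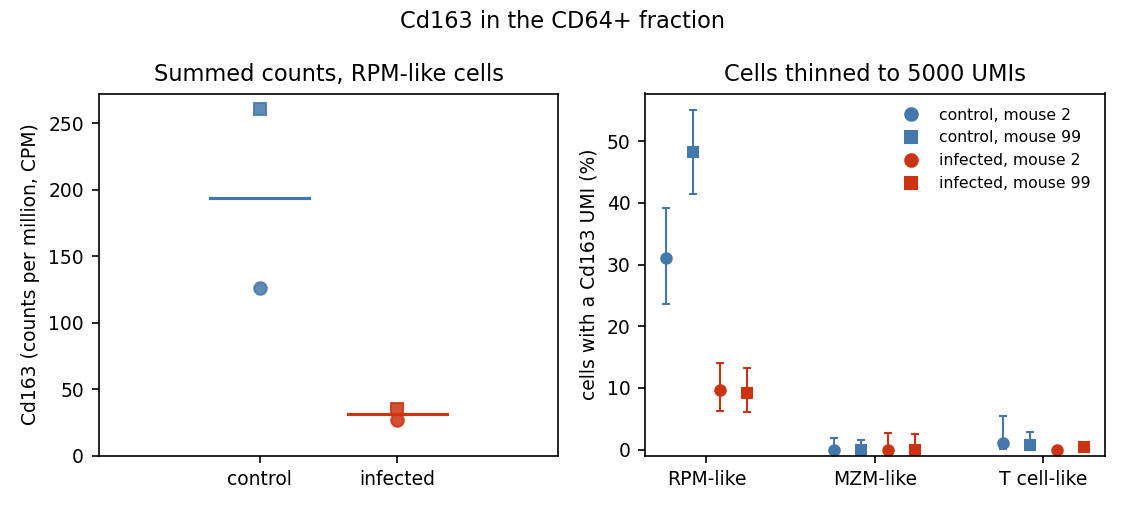
Cd163 in CPM of red pulp macrophage-like (RPM-like) sums, with lines at the means, and percent of cells with a Cd163 UMI after thinning, with exact 95% intervals, also in marginal zone/metallophilic macrophage-like (MZM-like) and T cell-like cells. The RPM-like shares were 31.0% and 48.2% in controls and 9.68% and 9.19% in infected mice.

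In red pulp macrophage-like cells, 4 of 16 tested genes of MHC class II presentation rose in infected mice. Cd74, the invariant chain that guides class II molecules, went from 2364 ± 237 to 4716 ± 456 CPM (log2 fold change 1.0, SE 0.13, adjusted p = 0.00073, edgeR QL test with BH, n = 2). The class II chains H2-Ab1 (1.07, SE 0.15, adjusted p = 0.00208) and H2-Eb1 (1.04, SE 0.15, adjusted p = 0.00392) rose alike. Their regulator Ciita had a log2 fold change of 1.25 (SE 0.23, adjusted p = 0.0174). None of the 16 fell over all genes, and 7 rose and 0 fell adjusted over the list alone (camera adjusted p = 3.0e-08; adjusted p = 0.405 with an estimated correlation). H2-Aa, at 751 ± 200 and 1458 ± 215 CPM, did not pass (adjusted p = 0.0566). The class II genes had 8, 6, 6 and 4 risen and 0, 1, 0 and 0 fallen over all genes with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

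Of 21 tested members of the phagocytosis and scavenging list, 1 rose and 3 fell in red pulp macrophage-like cells, and the list was not called (camera adjusted p = 0.625). The scavenger receptor Marco fell from 318 ± 80.8 to 112 ± 23.6 CPM (log2 fold change −1.50, SE 0.21, adjusted p = 0.0380, edgeR QL test). Timd4, which binds phosphatidylserine on dying cells, fell from 78.2 ± 18.9 to 21.8 ± 1.32 CPM (−1.87, SE 0.18, adjusted p = 7.8e-05). The scavenger receptor Msr1 rose from 5.35 ± 1.67 to 25.7 ± 2.17 CPM (2.33, SE 0.28, adjusted p = 0.00038), and the C-type lectin receptor Clec1b fell (−0.67, SE 0.12, adjusted p = 0.0115). Adjusted over the list alone 2 rose and 3 fell. Of 15 complement genes 1 rose and 1 fell, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.893). C4b rose from 5.89 ± 3.54 to 45.4 ± 6.73 CPM (3.10, SE 0.29, adjusted p = 9.8e-05). C2 fell from 54.8 ± 6.28 to 9.40 ± 2.35 CPM (−2.53, SE 0.21, adjusted p = 1.1e-05). Marco was no longer called after subtraction of free RNA (log2 fold change −1.91, adjusted p = 0.340), with doublets kept (−1.52, 0.0629) or with equal cell numbers per library (−1.85, 0.448). The phagocytosis list had 2, 2, 1 and 1 risen and 3, 3, 3 and 3 fallen and the complement list had 2, 1, 1 and 1 risen and 2, 2, 2 and 1 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

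In red pulp macrophage-like cells 2 of 22 cholesterol and lipid handling genes and 2 of 21 inflammatory cytokine and NF-kB genes fell, and 0 of either list rose. The apolipoprotein Apoc1 fell from 46.3 ± 8.72 to 3.18 ± 0.964 CPM (log2 fold change −3.88, SE 0.27, adjusted p = 1.6e-06, edgeR QL test) and the fatty acid desaturase Scd1 fell (−1.60, SE 0.30, adjusted p = 0.0177). In the lipid list 3 fell adjusted over the list alone (camera adjusted p = 1.7e-07; adjusted p = 0.315 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, fell from 27.1 ± 11.1 to 0.635 ± 0.193 CPM (−5.29, SE 0.48, adjusted p = 4.3e-05) and the chemokine Ccl3 fell (−2.67, SE 0.51, adjusted p = 0.0210). The inflammatory list had the same count adjusted over the list alone (camera adjusted p = 0.00065; adjusted p = 0.461 with an estimated correlation). The interferon-induced chemokine Cxcl10 rose (1.26, SE 0.22, adjusted p = 0.0120), as 1 of 2 risen among 28 interferon-gamma-induced genes, with 3 risen adjusted over the list alone (camera adjusted p = 6.7e-05; adjusted p = 0.517 with an estimated correlation). The lipid list had 0 risen and 4, 5, 4 and 2 fallen; the inflammatory list had 1, 2, 1 and 0 risen and 6, 3, 4 and 3 fallen; and the interferon-gamma-induced list had 4, 5, 5 and 0 risen and 0, 1, 0 and 1 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

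Among 25 iron and haem handling genes, 0 rose and 1 fell in red pulp macrophage-like cells, the cystine transporter Slc7a11 (log2 fold change −2.54, SE 0.45, adjusted p = 0.0120, edgeR QL test). The list had the same count adjusted over the list alone (camera adjusted p = 0.00031; adjusted p = 0.371 with an estimated correlation; fry adjusted p = 0.0446). The haem oxygenase Hmox1 was at 6411 ± 417 and 4930 ± 113 CPM (−0.38, adjusted p = 0.251), passing only without control mouse 2 (adjusted p = 0.0313) or control mouse 99 (7.7e-05). The iron exporter Slc40a1 (−0.08, SE 0.12), the red pulp macrophage transcription factor Spic (−0.28, SE 0.11), Vcam1 (0.05, SE 0.12), Siglec1 (0.43, SE 0.21), Fcgr1 (0.19, SE 0.13) and Ptprc (0.15, SE 0.12) did not pass. Cd5l, an apoptosis inhibitor of macrophages, did not pass (−0.39, adjusted p = 0.221) except without control mouse 99 (0.00024). Of 4 haemoglobin genes 1 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 1.4e-18; adjusted p = 0.315 with an estimated correlation), with Hbb-bt at 372 ± 43.5 and 90.2 ± 33.0 CPM. Haemoglobin made up 0.677% and 1.76% of the free RNA in control and 0.833% and 0.390% in infected libraries. Erythroid cell-like cells made up 0.914% and 2.27% of control and 0.613% and 0.161% of infected cells. Whether the haemoglobin RNA came from the red pulp cells themselves was not tested. The endothelial activation list, which holds Cd74, H2-Ab1 and Cxcl10, had 3 of 10 risen over all genes and 4 adjusted over the list alone (camera adjusted p = 3.6e-07; adjusted p = 0.371 with an estimated correlation). The extracellular matrix list had 1 of 4 fallen, the matrix protein Postn, also over the list alone (camera adjusted p = 0.0298; adjusted p = 0.461 with an estimated correlation; fry adjusted p = 0.0446). The other 14 of 23 lists were not called. The cell cycle list had 0 of 20 called over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.00148; adjusted p = 0.781 with an estimated correlation). The iron list had 0 risen and 5, 4, 1 and 1 fallen; the haemoglobin list had 0 risen and 4, 4, 4 and 4 fallen; the endothelial activation list had 4, 4, 4 and 3 risen and 0, 0, 0 and 1 fallen; and the cell cycle list had 0, 1, 0 and 0 risen and 17, 0, 0 and 1 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn. Postn was no longer called without infected mouse 2 (adjusted p = 0.290) or infected mouse 99 (0.346), which left 0 calls in the matrix list.

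The other leading genes of red pulp macrophage-like cells were Slc7a2, an arginine transporter (log2 fold change 1.07), Ypel2 (0.85), Cdk14 (0.84), Hivep2 (0.72), Tbc1d4 (0.66) and the membrane repair protein Dysf (0.63) among those higher. Among those lower were the calcium channel subunit Cacnb4 (−2.32), Adam23 (−1.95, from 562 ± 14.3 to 146 ± 26.6 CPM), 2900052N01Rik (−1.46), Colq (−1.0), Mtss1 (−1.0), the amino acid transporter Slc38a1 (−0.94), Ccser1 (−0.90) and Wdr75 (−0.89). Over 10622 genes tested, 20 rose and 48 fell in the edgeR QL test (1083 at an unadjusted p under 0.05), and DESeq2 called 10 and 33, with 34 genes called by both. The count was 350 without control mouse 2, 629 without control mouse 99 and 124 without infected mouse 2. Without infected mouse 99 the calls of Ciita (adjusted p = 0.0824), Cxcl10 (0.0566), Ccl3 (0.0507), Tbc1d4 (0.146) and Mtss1 (0.0876) were lost, and without infected mouse 2 that of Ypel2 (0.0787).

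**Figure D3:**
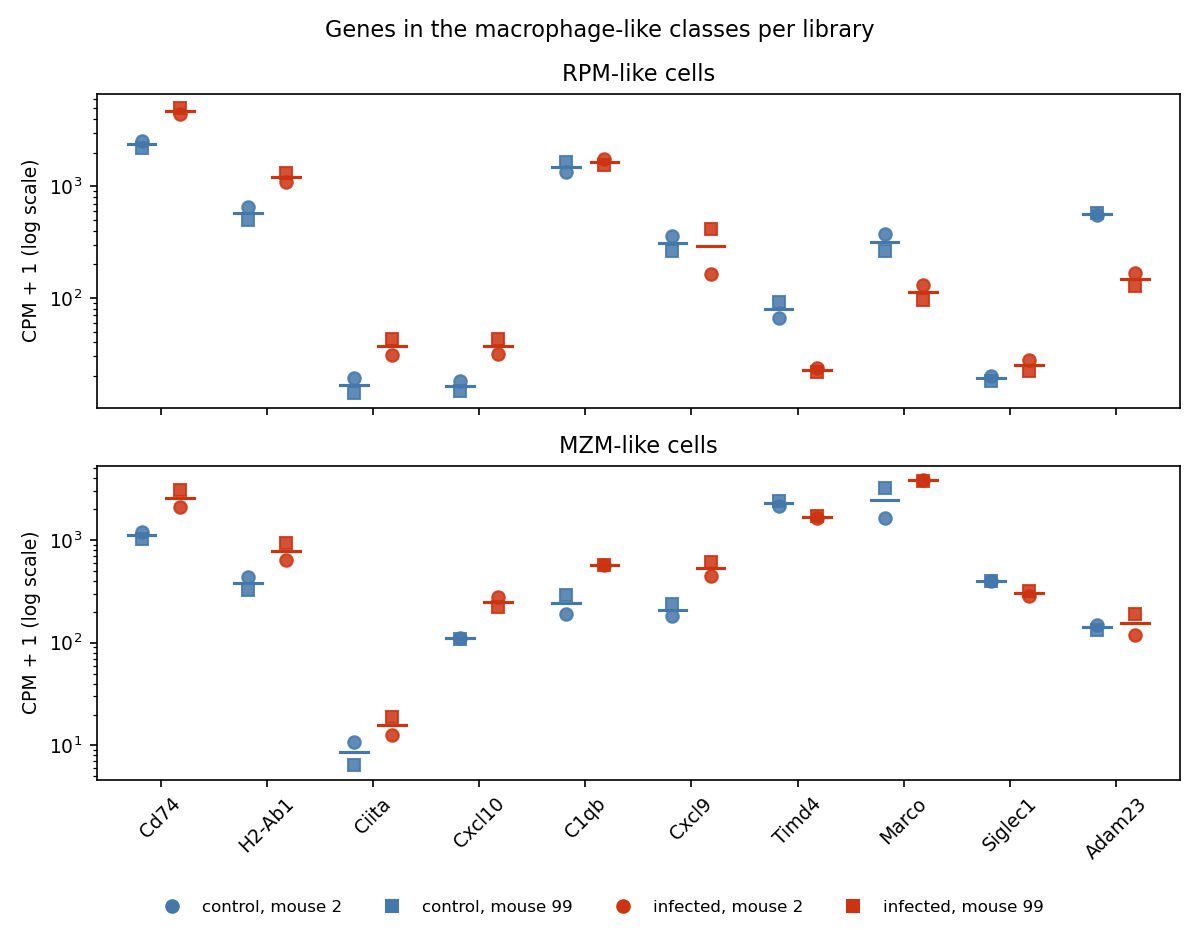
CPM plus 1, per library, of 10 genes in red pulp macrophage-like (RPM-like) and marginal zone/metallophilic macrophage-like (MZM-like) cells, with lines at the means of 2 mice. Ciita, Marco, Timd4, Siglec1 and Adam23 were not called in MZM-like cells, nor C1qb, Cxcl9 and Siglec1 in RPM-like cells.

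Marginal zone/metallophilic macrophage-like cells of infected mice had more RNA of complement C1q and of interferon-induced chemokines. C1qb rose from 241 ± 70.0 to 570 ± 6.17 CPM (log2 fold change 1.24, SE 0.17, adjusted p = 0.00117, edgeR QL test with BH, n = 2), with C1qa (0.91) and C1qc (0.94) also called. C2 fell from 197 ± 2.86 to 42.7 ± 8.74 CPM (−2.21, SE 0.14, adjusted p = 7.9e-07). Of 12 complement genes 4 rose and 1 fell, and 4 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0351; adjusted p = 0.417 with an estimated correlation). The T cell attracting chemokines Cxcl9, from 209 ± 40.4 to 528 ± 115 CPM (1.33, SE 0.17, adjusted p = 0.00077), and Cxcl10, from 110 ± 2.05 to 248 ± 39.2 CPM (1.18, SE 0.13, adjusted p = 0.00018), rose. They were the 2 risen of 29 interferon-gamma-induced genes, and 10 rose adjusted over the list alone (camera adjusted p = 3.3e-11; adjusted p = 0.327 with an estimated correlation). Of 20 chemokine and receptor genes 3 rose, Ccl12 among them (1.90, SE 0.32), and 4 fell, and 5 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.663). In the inflammatory list 0 rose and 3 fell of 22, with Cxcl1 at −1.72 (SE 0.30, adjusted p = 0.00603), and 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0129; adjusted p = 0.327 with an estimated correlation). The complement list had 4, 3, 3 and 5 risen and 1, 2, 1 and 2 fallen; the interferon-gamma-induced list had 3, 4, 5 and 2 risen and 0 fallen; the chemokine list had 3, 4, 4 and 3 risen and 2, 4, 2 and 3 fallen; and the inflammatory list had 1, 1, 1 and 0 risen and 1, 4, 3 and 2 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

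Of 15 class II genes 4 rose in marginal zone/metallophilic macrophage-like cells, as did 6 of 19 immediate-early and heat shock genes. Cd74 went from 1113 ± 131 to 2564 ± 696 CPM (log2 fold change 1.20, SE 0.18, adjusted p = 0.00179, edgeR QL test), and H2-Eb1 (1.04), H2-Ab1 (1.05) and the peptide loading chain H2-DMa (0.72) were called. No class II gene fell, and 7 rose adjusted over the list alone (camera adjusted p = 3.4e-09; adjusted p = 0.327 with an estimated correlation). These calls depended on single mice: Cd74 had an adjusted p of 0.417 without control mouse 2 and 0.419 without control mouse 99. H2-Eb1 had 0.141 and 0.240, and H2-Ab1 0.385 and 0.457, without the same mice, and without infected mouse 99 H2-Ab1 had 0.0558 and H2-DMa 0.116. The phosphatase Dusp1 (1.25, SE 0.16), the chaperone partner Dnajb1 (1.24, SE 0.16) and the transcription factors Atf3 (1.41, SE 0.21) and Ier2 (0.91, SE 0.16) rose. The immediate-early and heat shock list had 11 risen adjusted over the list alone and 0 fallen (camera adjusted p = 3.4e-21; adjusted p = 0.327 with an estimated correlation). In the phagocytosis list 3 rose and 0 fell of 22, Clec1b among them (0.85, SE 0.16), and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00069; adjusted p = 0.327 with an estimated correlation). The class II list had 1, 2, 7 and 2 risen and 0 fallen; the immediate-early list had 10, 9, 7 and 10 risen and 0 fallen; and the phagocytosis list had 1, 4, 1 and 5 risen and 1, 2, 0 and 0 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

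Among the leading lower genes of marginal zone/metallophilic macrophage-like cells, the collagen Col6a5 fell from 75.1 ± 16.3 to 3.84 ± 0.941 CPM (log2 fold change −4.30, SE 0.25, adjusted p = 3.4e-07, edgeR QL test). N-cadherin Cdh2 fell (−2.89, SE 0.19), and the neuronal nitric oxide synthase Nos1 fell from 89.7 ± 2.47 to 13.3 ± 0.356 CPM (−2.75, SE 0.16, adjusted p = 3.4e-07). The calcium release channel Ryr3 (−2.17), Tesc (−2.14), the complement receptor Cr2 (−2.10), Il22ra2, a soluble binding protein of interleukin 22 (−2.09), Zfp804b (−1.97) and Ppp1r9a (−1.95) also fell. The lipoprotein lipase Lpl (−1.61, SE 0.17) and Apoc1 (−2.47, SE 0.35) fell as 2 of 3 fallen among 21 lipid genes, 0 rising over all genes and 1 rising and 3 falling adjusted over the list alone (camera adjusted p = 0.349). Elastin Eln fell (−1.37, SE 0.19) as 1 of 8 extracellular matrix genes, with the same count adjusted over the list alone (camera adjusted p = 0.00556; adjusted p = 0.327 with an estimated correlation). In the endothelial activation list, with Cxcl9 and Cxcl10 among its members, 4 rose and 1 fell of 11, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.4e-09; adjusted p = 0.327 with an estimated correlation). The other 14 of 23 lists were not called. The potassium channels Kcnk13 (1.45) and Kcnj10 (1.06), Bank1 (1.20) and Rnf217 (1.16) were the remaining leading genes that rose. The immunoglobulin constant gene Ighg2c was at 1.85 ± 1.09 and 25.7 ± 12.6 CPM (3.84, SE 0.45), 1 of 8 immunoglobulin genes that rose, also over the list alone (camera adjusted p = 0.0171; adjusted p = 0.327 with an estimated correlation). In the summed fraction Ighg2c went from 122 ± 68.6 to 2672 ± 509 CPM, and in the marginal zone/metallophilic class it was not among the genes tested after subtraction of free RNA. Of the free RNA, Ighm, Ighd, Igkc, Iglc1, Iglc2, Iglc3 and Jchain together made up 0.744% and 0.395% in control and 0.610% and 0.605% in infected libraries. These hold no Ighg gene, so they do not measure free Ighg2c RNA. Plasma cell-like cells made up 1.29% and 0.487% of control and 1.11% and 1.15% of infected cells. The lipid list had 0 risen and 3, 3, 2 and 2 fallen; the matrix list had 0 risen and 1, 2, 1 and 1 fallen; the endothelial activation list had 2, 2, 5 and 3 risen and 0, 1, 1 and 0 fallen; and the immunoglobulin list had 2, 1, 1 and 1 risen and 0 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

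The class's own marker Siglec1, the sialoadhesin of metallophilic macrophages, did not pass (397 ± 4.95 and 304 ± 24.9 CPM, log2 fold change −0.39, adjusted p = 0.176, edgeR QL test). Nor did Spic (−0.06, SE 0.13), Vcam1 (0.16, SE 0.13), Slc40a1 (0.28, SE 0.23), Ptprc (0.17, SE 0.13), Fcgr1 (2.16 ± 1.03 and 3.09 ± 1.92 CPM, SE 0.59) and Hmox1 (−0.34, SE 0.15). Hmox1 passed only without control mouse 2 (−0.54, adjusted p = 0.0105). Cd5l had 0.35 (SE 0.36) and passed only without control mouse 99 (0.95, adjusted p = 0.00359). The marginal zone lectin Cd209d, chosen after its values were seen, rose (0.97, SE 0.15, adjusted p = 0.00263). Over 10454 genes, 75 rose and 116 fell (1141 at an unadjusted p under 0.05), DESeq2 called 47 and 60, and 96 genes were called by both. The count was 372 without control mouse 99.

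The infection effect itself was compared between classes of the CD64-positive fraction through an interaction term. Between red pulp and marginal zone/metallophilic macrophage-like cells it differed for 140 of 11439 genes (edgeR QL interaction with the mouse as a block; 1088 at an unadjusted p under 0.05). Of 131 of these tested in both classes, 93 had fold changes of opposite sign. These genes were picked for a difference between the classes, so opposite signs among them are partly built in. Of 9757 genes tested in both classes, 6 were called higher in both, Cd74 and Cxcl10 among them. Another 9 were called lower in both, C2 and Apoc1 among them. Independent calls would give 0.11 and 0.22, but the 2 classes come from the same mice. The red pulp effect was lower for Timd4 (−1.38, SE 0.16, adjusted p = 1.9e-06), C1qb (−1.10, SE 0.13, adjusted p = 2.4e-06), C1qc (−1.01), C1qa (−0.90), Clec1b (−1.50), the transcription factor Jun (−2.68), Atf3 (−1.77), Dusp1 (−1.64) and Ptgs2 (−6.50). It was higher for Nos1 (2.91, SE 0.29, adjusted p = 6.0e-08) and Lpl (1.55). Without control mouse 99 the count was 387, and without infected mouse 2 it was 87. Against classical monocyte-like cells 11 genes differed, among them Cxcl10 (3.00, SE 0.29) and Msr1 (2.88, SE 0.29), both higher in effect in red pulp cells.

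Within red pulp macrophage-like cells, cells with a Cd163 UMI were compared with cells without one in the same 4 mice. Cd163-positive cells numbered 45 and 106 in control mice 2 and 99 and 24 and 25 in infected mice 2 and 99. The positive sums of infected mice thus hold few UMIs of any gene at low CPM. The lipid-binding gene Apol7c was 0.486 ± 0.973 CPM in Cd163-positive and 46.2 ± 49.3 CPM in Cd163-negative cells (SD, n = 4). It was lower in 4 of 4 mice (log2 fold change −5.89, SE 0.69, adjusted p = 8.2e-14, edgeR QL test with the mouse as a block). In infected mouse 2 it was at 0 CPM in positive and 6.43 CPM in negative cells, too few UMIs to show a difference in that mouse. The ubiquitin-like modifier Ubd was 117 ± 35.0 and 239 ± 57.4 CPM (−1.11, SE 0.17, adjusted p = 1.7e-07), lower in 4 of 4 mice. Ubd was called with each mouse left out, and Apol7c with each but control mouse 99, without which it was not tested. Apol7c was also a leading gene of the conventional dendritic cell-like cluster, Marco and Pla2g2d of the marginal zone/metallophilic macrophage-like cluster, and Ubd, Marco and Pla2g2d of cluster 24. Cxcl9 (−2.92, SE 0.31), Marcksl1 (−1.53), Marco (−0.96), Plbd2 (−0.94), Serpina3g (−0.84), the phospholipase Pla2g2d (−0.70), Hbb-bs (−0.45) and Crip1 (−0.39) were also lower, and Brap (1.36), Ttc28 (1.04), Adamdec1 (0.54), Tbc1d4 (0.50) and the histone deacetylase Hdac9 (0.35) were higher in Cd163-positive cells. These differences had the same direction in 4 of 4 mice, except for Serpina3g, lower in 3 of 4, and Hbb-bs, lower in 2 and higher in 2, the infected mice. Of 24 interferon-gamma-induced genes 0 were higher and 3 lower, and 5 lower adjusted over the list alone (camera adjusted p = 1.4e-11; adjusted p = 0.145 with an estimated correlation). Of these genes 3, 2, 2 and 1 were lower and 0 higher with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

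In that comparison 5 genes were higher and 10 lower of 7178 tested (389 at an unadjusted p under 0.05), and DESeq2 with the mouse as a block called 0 and 1. The count was 6 without control mouse 2, 7 without control mouse 99 and 6 without infected mouse 99, and 2 without the mouse block. The call of Cxcl9 was lost without infected mouse 2 (adjusted p = 0.515) or infected mouse 99 (0.945), and those of Marco (0.767) and Pla2g2d (0.206) without control mouse 2. The 10 other called genes named beside Apol7c and Ubd each lost the call without at least 1 mouse, with adjusted p values of up to 0.999 for Hbb-bs without control mouse 2. The difference between Cd163-positive and -negative cells differed with infection for Cdk8 (1.02, SE 0.21, adjusted p = 0.00867) and Hbb-bs (0.97, SE 0.22, adjusted p = 0.0294), and 0 genes were called without control mouse 2 or control mouse 99.

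The monocyte-like, lymphocyte-like and other classes of the CD64-positive fraction gave few calls. In classical monocyte-like cells Cxcl10 fell from 88.5 ± 4.29 to 26.1 ± 3.70 CPM (log2 fold change −1.76, SE 0.22, adjusted p = 0.0101, edgeR QL test) as 1 of 2 calls. The other was Ubash3b (−1.09), lost without infected mouse 2 (adjusted p = 0.118). The counts without control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 were 36, 194, 11 and 7 calls. In non-classical monocyte-like cells 5 genes rose, Hivep2 (1.09, SE 0.17) and Ighg2c (2.60, SE 0.44) among them, and Arid5b fell (−0.86). The counts with the mice left out in the same order were 90, 250, 17 and 5, and Arid5b was lost without infected mouse 2 (adjusted p = 0.131) or infected mouse 99 (0.140). B cell-like cells had 5 higher and 9 lower genes (270, 711, 5 and 0 in the same order), with Cirbp, a cold-inducible RNA-binding protein, at −1.0 (SE 0.15), lost without infected mouse 2 (0.138) or infected mouse 99 (0.393). T cell-like cells had 0 calls in edgeR, 702 at an unadjusted p under 0.05 and 5 and 5 in DESeq2 (97, 505, 5 and 3 in the same order). Cluster 10, led by H2-M2 and Retnla, had 0 calls in edgeR, 412 at an unadjusted p under 0.05 and 1 and 1 in DESeq2 (103, 191, 2 and 1).

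In cluster 14 of the CD64-positive fraction, which was led by Dscam and Ctnnd2, Ccdc162 fell from 114 ± 21.8 to 4.46 ± 0.0628 CPM (log2 fold change −4.58, SE 0.51, adjusted p = 0.00143, edgeR QL test) as the single call. Fibroblast-like cells had a single call, the adhesion molecule Sdk1, from 5.79 ± 2.92 to 90.2 ± 7.30 CPM (3.83, SE 0.44, adjusted p = 0.0446). Cluster 6, with the T and natural killer cell genes Ccl5 and Nkg7 in the lead, had 4 higher genes, the lipid flippase Atp8a2 among them (3.88, SE 0.52, adjusted p = 0.00118), and 1 lower in edgeR, with 0 in DESeq2. Cluster 11, led by the cycling genes Top2a and Mki67 and Ighg3, had 3 higher and 2 lower genes, with Tox at 2.08 (SE 0.18, adjusted p = 0.0137), a call lost without infected mouse 99 (0.181). With control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn, the counts were 38, 47, 8 and 14 in cluster 14, 286, 5, 5 and 2 in fibroblast-like cells, 28, 19, 9 and 7 in cluster 6, and 324, 181, 8 and 0 in cluster 11. Conventional dendritic cell-like cells had 1 higher gene, and 0, 4, 45 and 104 in the same order.

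Endothelial cell-like cells of the CD45-negative fraction, which carried the sinus endothelial gene Stab2, had 8 of 19 genes of MHC class I presentation higher and 0 lower in infected mice. The immunoproteasome subunit Psmb8 rose from 158 ± 10.0 to 257 ± 21.6 CPM (log2 fold change 0.71, SE 0.09, adjusted p = 0.00061, edgeR QL test with BH, n = 2). It rose beside Psmb9 (0.62), Psmb10 (0.50) and the class I genes H2-Q6 (1.05, SE 0.11, adjusted p = 8.9e-05), H2-Q7 (0.64) and H2-Q4 (0.61). Adjusted over the list alone 12 rose (camera adjusted p = 8.8e-15; adjusted p = 0.188 with an estimated correlation; fry adjusted p = 0.0257). The interferon-induced GTPase Igtp rose (0.92, SE 0.17) as 1 of 5 risen among 25 interferon-gamma-induced genes, with 6 adjusted over the list alone (camera adjusted p = 3.1e-07; adjusted p = 0.400 with an estimated correlation). The nucleic acid sensor Zbp1 rose (1.62, SE 0.21), the single call among 27 type I interferon-stimulated genes, also over the list alone (camera adjusted p = 0.0279; adjusted p = 0.692 with an estimated correlation). The class II helper H2-DMb1 rose from 0.857 ± 0.641 to 9.46 ± 2.32 CPM (3.39, SE 0.52), 1 of 10 class II genes over all genes and 7 adjusted over the list alone (camera adjusted p = 3.5e-10; adjusted p = 0.400 with an estimated correlation). The class I list had 8, 9, 6 and 7 risen and 0 fallen; the interferon-gamma-induced list had 5, 4, 7 and 4 risen and 0 fallen; the type I interferon list had 2, 1, 1 and 1 risen and 0, 0, 0 and 1 fallen; and the class II list had 5, 3, 6 and 4 risen and 0 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

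Of 14 extracellular matrix genes 0 rose and 6 fell in endothelial cell-like cells. Col15a1 fell from 46.0 ± 9.08 to 4.33 ± 0.0204 CPM (log2 fold change −3.39, SE 0.24, adjusted p = 1.5e-06, edgeR QL test), and Col5a2 (−1.94, SE 0.24) and Col4a2 (−0.92, SE 0.10) fell. Adjusted over the list alone 9 fell (camera adjusted p = 2.5e-14; adjusted p = 0.188 with an estimated correlation; fry adjusted p = 0.0109). The sialomucin Cd34 fell from 84.0 ± 8.53 to 35.4 ± 0.855 CPM (−1.24, SE 0.13, adjusted p = 8.0e-05). The surface protein Ly6c1 (−0.66, SE 0.09) and the cholesterol synthesis enzyme Sqle (−0.91, SE 0.15) also fell. Of 20 lipid genes 1 rose and 2 fell, and 2 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.0850). The cadherin Cdh6 (−1.76), Tmem178b (−1.34), Sv2c (−1.28), Srgap3 (−1.28), Sema6d (−1.25), Dram1 (−1.20) and Ceacam10 (−1.20) fell as well. The matrix list had 0 risen and 4, 5, 5 and 4 fallen and the lipid list had 1, 1, 1 and 2 risen and 5, 2, 2 and 5 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn.

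Pla2g7, the platelet-activating factor hydrolase, rose in endothelial cell-like cells from 46.8 ± 4.60 to 136 ± 17.0 CPM (log2 fold change 1.52, SE 0.13, adjusted p = 7.2e-06, edgeR QL test). The fatty acid carrier Fabp4 (1.24), the phosphodiesterase Pde10a (1.12), the cell cycle inhibitor Cdkn2c (1.08), Mal (0.90), Pnmal2 (0.84), Runx1t1 (0.83), Plxdc1 (0.83) and Fxyd6 (0.82) also rose. Pnmal2 was no longer called without infected mouse 99 (adjusted p = 0.0972). Vcam1, at 166 ± 19.9 and 234 ± 39.2 CPM, did not pass (0.48, SE 0.12, adjusted p = 0.0598), except without control mouse 99 (0.00641) or infected mouse 99 (0.00013). Among 18 glycolysis and hypoxia genes 2 rose, and 6 rose adjusted over the list alone (camera adjusted p = 0.00298; adjusted p = 0.400 with an estimated correlation; fry adjusted p = 0.0389). Of 17 immediate-early genes, with Dnajb1 rising (0.90), 2 rose and 1 fell, and 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00368; adjusted p = 0.543 with an estimated correlation). Of 9 TGF-beta target genes 2 fell, and 3 fell adjusted over the list alone (camera adjusted p = 0.00328; adjusted p = 0.400 with an estimated correlation). Of 13 mitochondrially encoded genes 2 fell, and 5 fell adjusted over the list alone (camera adjusted p = 0.00052; adjusted p = 0.671 with an estimated correlation). In the endothelial activation list Ly6c1 alone was called of 12, while 5 rose and 1 fell adjusted over the list alone and camera called it higher (adjusted p = 0.0401; adjusted p = 0.400 with an estimated correlation). The glycolysis list had 2, 2, 1 and 2 risen and 0 fallen; the immediate-early list had 1, 6, 2 and 5 risen and 2, 0, 0 and 1 fallen; the TGF-beta list had 0 risen and 1, 1, 1 and 1 fallen; the mitochondrial list had 0, 1, 0 and 0 risen and 8, 2, 1 and 1 fallen; and the endothelial activation list had 3, 3, 2 and 4 risen and 1, 1, 1 and 1 fallen, with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn. Over 11059 genes, 142 rose and 207 fell (1643 at an unadjusted p under 0.05), DESeq2 called 67 and 95, and 143 genes were called by both.

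**Figure D4:**
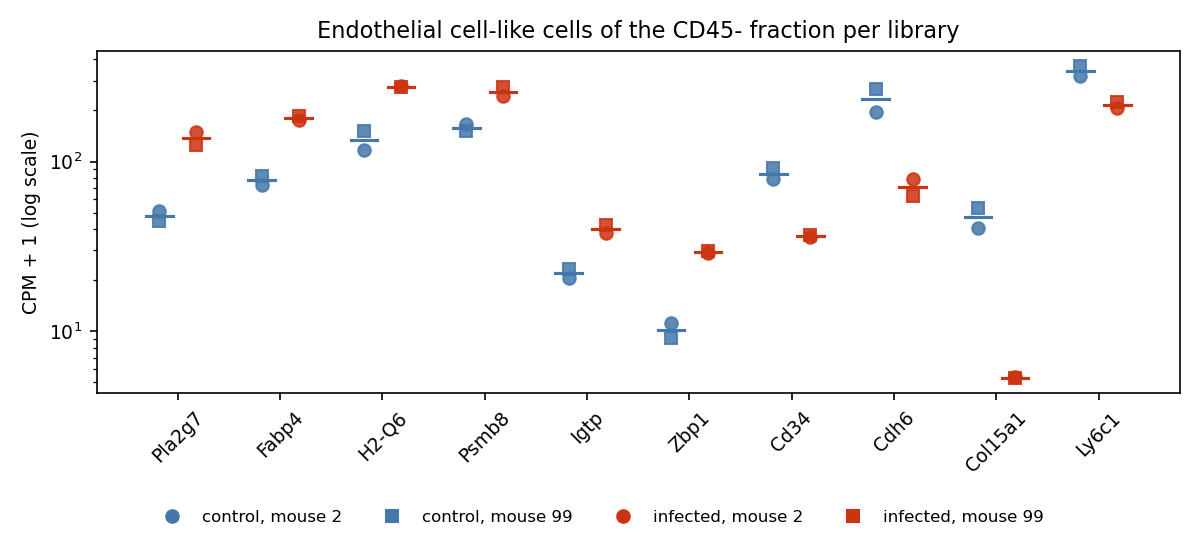
CPM plus 1, per library, of 10 genes in endothelial cell-like cells of the CD45-negative fraction, with lines at the means of 2 mice. All 10 were called, Psmb8 with a log2 fold change of 0.71 and Col15a1 with one of −3.39.

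In haemoglobin-low erythroid-like cells 3 of 21 iron and haem genes rose modestly in infected mice. The iron storage chain Ftl1 rose (log2 fold change 0.47, SE 0.05, adjusted p = 0.00662, edgeR QL test). The transferrin receptor Tfrc (0.33) and the biliverdin reductase Blvrb (0.32) were the other two, with 8 risen adjusted over the list alone (camera adjusted p = 0.00640; adjusted p = 0.757 with an estimated correlation). The iron list had 6, 4, 0 and 0 risen with control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn. The mitochondrial iron importer Slc25a37 rose (0.51, SE 0.08), and the metallothioneins Mt2 (−0.54, SE 0.05) and Mt1 (−0.35, SE 0.05) fell. The class pools 6 clusters whose mix differed between the groups. Clusters 7 and 10, with more Hbb-bs RNA than the other 4, held 17.1% and 12.1% of the class in control mouse 2 and 13.7% and 6.07% in control mouse 99. They held 22.7% and 17.6% in infected mouse 2 and 20.2% and 17.4% in infected mouse 99. Mt1 and Mt2 were leading genes of clusters 3 and 4. In all, 52 genes rose and 41 fell of 12956 tested, or 55.9% higher, against 56 and 236 (19.2% higher) when scaled by library totals, and DESeq2 called 383 and 190. The count was 1101 without control mouse 2, 523 without control mouse 99, 7 without infected mouse 2 and 6 without infected mouse 99. The calls of Ftl1, Slc25a37, Mt1 and Mt2 were lost without infected mouse 2 (adjusted p 0.175 to 0.550) and without infected mouse 99 (0.136 to 0.247). Haemoglobin-high erythroid-like cells had 0 calls in edgeR, 447 at an unadjusted p under 0.05 and 2 and 6 in DESeq2, and the counts were 1887 without control mouse 2, 557 without control mouse 99 and 1 without infected mouse 99.

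Basophil/mast cell-like cells had 9 genes higher and 14 lower in infected mice in edgeR and 0 and 2 in DESeq2. The granule protease Prss34 rose from 17262 ± 855 to 23895 ± 1049 CPM (log2 fold change 0.47, SE 0.07, adjusted p = 0.00039, edgeR QL test). Granzyme B, Gzmb, fell from 804 ± 201 to 171 ± 51.9 CPM (−2.24, SE 0.21, adjusted p = 9.4e-06). Neutrophil-like cells had 16 higher and 5 lower (76.2% higher, against 57.1% with library totals). In these the antibacterial protein Pglyrp1 (0.65, SE 0.10, adjusted p = 0.00291) and the oxidase subunit Cybb (0.76, SE 0.12, adjusted p = 0.00354) rose. Hbb-bs, a red blood cell transcript, went from 650 ± 99.8 to 2104 ± 83.5 CPM (1.70, SE 0.11). Cluster 26, with a median of 1757.5 UMIs, held 42.1% of the neutrophil-like cells of infected mouse 2, against 2.96% to 4.62% in the other mice. In cluster 14, led by Ly6c2 and Mpo, which mark early myeloid cells, the class II genes H2-Eb1 (−2.35, SE 0.30, adjusted p = 0.0146) and H2-Ab1 (−1.16, SE 0.17, adjusted p = 0.0126) and the interferon-induced Epsti1 (−1.18, SE 0.17) fell, among 4 higher and 10 lower. With control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn, the counts were 12, 24, 12 and 40 in basophil/mast cell-like cells, 67, 142, 27 and 86 in neutrophil-like cells, and 292, 64, 131 and 67 in cluster 14.

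Of the unnamed clusters that shrank in the CD45-negative fraction, cluster 5 had 11 genes higher and 18 lower and cluster 8 had 4 and 17. The chaperone Hsph1 rose in cluster 5 (log2 fold change 0.81, SE 0.11, adjusted p = 0.00811, edgeR QL test) and the vessel growth factor Angpt1 fell (−0.64, SE 0.08, adjusted p = 0.00444). Each call was lost without infected mouse 2 (adjusted p 0.217 and 0.368) or infected mouse 99 (0.241 and 0.225). In cluster 8 the transcription factor Nfia fell (−0.68, SE 0.11, adjusted p = 0.00114), lost without control mouse 2 (0.0532) or control mouse 99 (0.0531). Cluster 12 had 29 higher and 17 lower (63.0% higher, against 51.2% with library totals), the itaconate enzyme Acod1 among the higher (1.51, SE 0.18, adjusted p = 0.00066), and 0 calls without control mouse 2 (Acod1 adjusted p = 0.621) or control mouse 99 (0.677). The platelet chemokine Pf4 (2.54, SE 0.25, adjusted p = 0.00071) was among 3 genes that rose in cluster 2. Megakaryocyte/platelet-like cells had 0 calls in edgeR, 952 at an unadjusted p under 0.05 and 19 and 2 in DESeq2, and 494 without infected mouse 2 and 644 without infected mouse 99. Cluster 17, with a median of 1496 UMIs, had 0 in edgeR, 145 at an unadjusted p under 0.05, 0 in DESeq2 and up to 47 without control mouse 2; library totals moved the median log2 fold change of all its genes to 0.15. In the order used above, the counts were 53, 136, 3 and 3 in cluster 5, 5, 37, 24 and 48 in cluster 8, 23 and 32 without the infected mice in cluster 12, and 1, 34, 69 and 21 in cluster 2.

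Sums over all cells moved with the class shares as well as with expression. In the CD64-positive fraction 322 genes rose and 636 fell of 16011. The T cell genes Lef1 (log2 fold change 1.71, SE 0.22, adjusted p = 0.0218, edgeR QL test), Bcl11b (1.65) and Cd8a (1.36) rose, and Siglec1 (−1.41), Timd4 (−1.62), Dclk1 (−2.54) and Colec12 (−2.36) fell, alongside the shift in T cell-like and marginal zone/metallophilic shares. Ighg2c rose from 122 ± 68.6 to 2672 ± 509 CPM (4.45, SE 0.50). The count was 2743 without control mouse 2, 2787 without control mouse 99, 22 without infected mouse 2 and 17 without infected mouse 99, and of the genes named Dclk1 and Colec12 were called each time. In the CD45-negative fraction 487 rose and 515 fell of 16798, with Acp5 (1.38, SE 0.10, adjusted p = 0.0218), Mgst3 (1.24) and Uros (1.05) rising and Angpt1 (−1.59) and Crip1 (−0.97) falling. Scaling by library totals moved the median of all genes to −0.15 and the split to 292 and 879 (24.9% higher, against 48.6%). The count was 0 without control mouse 2 or control mouse 99, and 2493 without infected mouse 99. DESeq2 called 617 and 924 genes in the CD64-positive and 1354 and 873 in the CD45-negative fraction.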

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

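The tests of free RNA, dilution, a Cd163-positive kind of cell and marginal zone macrophage RNA, the splits of the Cd163 sums and the reporter values were chosen only after the result was seen, whereas the tests of B cell RNA, dendritic cell RNA and a variant at the H2 region were written down before.

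Cd163 was lower in red pulp macrophage-like cells of both infected mice than of both control mice. Free RNA is argued against, since the upper bound of the share of control T cell-like cells with a Cd163 UMI reached 5.45% and the lowest lower bound of the red pulp class was 23.6%. Dilution by cells that lack the other markers of the class is argued against as well. The median log2 fold change of 16 such markers was −0.081 (range −0.64 to 0.22), against −1.67 for Cd163 plus 2 SE. These markers named the class, so dilution by cells that carry them but not Cd163 was not tested. Whether fewer cells of a Cd163-positive kind were present or each cell held less Cd163 RNA cannot be told apart. Fewer cells of a Cd163-positive kind would move the genes called between Cd163-positive and -negative cells toward the Cd163-negative level. Of 15 such genes, 2 moved that way with infection and the others moved away from it (two-sided exact binomial p = 0.00739). No conclusion is drawn from this, since the splits of the sums are too few to test those 15 calls. The binomial test also takes the genes as independent.

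Class II genes were higher in infected red pulp and marginal zone/metallophilic macrophage-like cells. B cell RNA is argued against, since the summed B cell markers rose by at most 0.994% of what the rise in Cd74 would need, and dendritic cell RNA likewise, at 0.874%. For the chains H2-Aa, H2-Ab1 and H2-Eb1, a variant at the H2 region that acts alike in all cell types is argued against. The median log2 fold change of H2-Aa, H2-Ab1 and H2-Eb1 was 0.10 in B cell-like cells and 1.04 in red pulp macrophage-like cells (largest SE 0.18). A variant that acts in macrophages and not in B cells would not show in these values and was not tested. C2 fell and C4b rose in red pulp macrophage-like cells. Both lie on chromosome 17, as those chains do, and neither was part of this test. Cd74 and Ciita, which lie on chromosomes 18 and 16, rose in red pulp macrophage-like cells too. A response of these macrophages to infection may remain as a hypothesis, found and tested on the same data.

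Timd4 and Marco were lower in infected red pulp macrophage-like cells. RNA or cells with the average profile of the marginal zone/metallophilic class are argued against. The loss was 2.47% (SE 0.596) of the level in that class for Timd4 and 8.46% (SE 2.41) for Marco, against a median of 0.108% for 13 other leading genes. Of these Pla2g2d lost 5.22% (SE 1.78) and Colq 3.57% (SE 1.04), while Dclk1 lost 0.108% (SE 0.0275) and Fgf14 0.0553% (SE 0.0669). The average profile would bring all of them alike. A subset of the class rich in Marco and Pla2g2d was not tested, nor was cluster 24, which had both among its leading genes. Free RNA is argued against for Timd4, as 116% of its log2 fold change was left after subtraction (−2.16, SE 0.23, adjusted p = 0.00061). For Marco 127% was left (−1.91, SE 0.40, against −1.50, SE 0.21, before), but the larger SE ended the call (adjusted p = 0.340), so free RNA and a lower level in the cells cannot be told apart.

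The split into Cd163-positive and -negative sums gave 15 genes, and 1 of the 8 splits that part the sums of every mouse, the real one, gave as many, with 5 genes in the highest other. These splits are too few for a share under 0.05. Of the splits that part no mouse, which were fitted without the mouse as a block and count the 2 sums of a mouse as separate samples, infected against control gave 74 genes and the others 0 and 4. These counts cannot be set beside the 15.

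The infection effect differed by a test of the difference itself between red pulp macrophage-like cells and marginal zone/metallophilic macrophage-like cells for 140 genes, B cell-like cells for 64, non-classical monocyte-like cells for 26, cluster 6 for 19, T cell-like cells for 11, classical monocyte-like cells for 11, cluster 11 for 6, fibroblast-like cells for 6, cluster 10 for 4, cluster 14 for 4 and conventional dendritic cell-like cells for 2. With control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn, the counts were 155, 387, 87 and 138 for the first, 291, 507, 43 and 26 for B cell-like cells, 73, 193, 13 and 11 for non-classical monocyte-like cells, 40, 41, 20 and 4 for cluster 6, and 60, 121, 6 and 0 for T cell-like cells. In the same order they were 30, 22, 9 and 7 for classical monocyte-like cells, 321, 37, 5 and 16 for cluster 11, 222, 44, 0 and 0 for fibroblast-like cells, 71, 52, 14 and 22 for cluster 10, 49, 36, 0 and 4 for cluster 14, and 111, 17, 13 and 25 for dendritic cell-like cells.

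Against marginal zone/metallophilic macrophage-like cells, the difference in log2 fold change was −1.38 for Timd4, −1.10 for C1qb, −1.01 for C1qc, −0.90 for C1qa, 2.91 for Nos1, 1.55 for Lpl, −1.64 for Dusp1, −1.77 for Atf3, −1.50 for Clec1b, −2.68 for Jun and −6.50 for Ptgs2. Against B cell-like cells it was −1.06 for Marco and 1.24 for Ciita, neither called without infected mouse 99 (adjusted p = 0.227 and 0.125). Against classical monocyte-like cells it was 3.00 for Cxcl10 and 2.88 for Msr1. Against non-classical monocyte-like cells it was 2.78 for Msr1, −1.07 for Hmox1 and −3.25 for Cxcl9, the last 2 not called without infected mouse 99 (adjusted p = 0.489 and 0.859) and Cxcl9 also not without control mouse 2 (0.0699). The difference between Cd163-positive and -negative cells differed with infection for 2 genes, Cdk8 (1.02) and Hbb-bs (0.97).

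The tdTomato reporter, which marks descendants of Ms4a3-expressing progenitors and is not named in the comparisons above, was called higher in CD45-negative cluster 12 (log2 fold change 1.22, SE 0.28, adjusted p = 0.0429). That call was lost without control mouse 2 (adjusted p = 0.621), control mouse 99 (0.677) or infected mouse 2 (0.340) and after subtraction of free RNA (0.702). In summed red pulp macrophage-like cells the reporter did not pass (1.57, SE 0.53, adjusted p = 0.284). It was seen after thinning in 2.42% and 2.94% of infected red pulp macrophage-like cells (mean 2.68%) against 0.690% and 0.909% of control cells. Thinned to 2500 UMIs instead, the groups overlapped, with 1.13% and 2.35% of infected cells (mean 1.74%) against 1.20% and 0.858% of control cells. In marginal zone/metallophilic macrophage-like cells it was seen in 2.27% and 1.38% of infected cells (mean 1.83%) and in 0% of control cells, which allows up to 1.47% and 1.22%. Without thinning it was seen in 6.92% and 5.86% of infected and 1.02% and 3.01% of control red pulp macrophage-like cells, and in 5.97% and 5.44% of infected and 0% of control marginal zone/metallophilic macrophage-like cells. Classical monocyte-like cells had 0.980% and 4.69% in controls and 0.746% and 4.73% in infected mice, and non-classical monocyte-like cells 2.13% and 2.22%, and 1.98% and 4.55%. All called CD64-positive cells together held 27 and 27 tdTomato UMIs in control and 58 and 68 in infected libraries. A cell without a UMI may thus still carry the reporter, and these shares do not give the share of labelled cells. B cell-like cells had 0% in all 4 libraries, which allows up to 0.775%, and T cell-like cells 0.115% in infected mouse 99 and 0% elsewhere. The exact 95% intervals of infected and control red pulp cells overlapped (0.893% to 5.19% and 1.28% to 5.71%, against 0.0175% to 3.78% and 0.110% to 3.25%).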

How the results depend on the processing

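The tests with all lymphoid classes left out, cluster 24 counted as marginal zone/metallophilic, the low-UMI cluster left out, and the scaling and filter alternatives of the Cd163 comparisons were chosen only after the result was seen; the rest were planned. Of the values of the comparisons under alternatives, 80 kept their direction and side of the threshold or their count within 1.5 times, 66 moved and 4 passed the threshold newly. Of 264 named genes past the threshold, 262 kept their direction under every alternative run for them and 82 kept their call. Of 22 others, 16 kept their direction.

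Called genes were 68 in red pulp and 191 in marginal zone/metallophilic macrophage-like cells, 35 in the other CD64-positive classes together, 958 in that fraction summed, 599 in the CD45-negative classes, 1002 in that fraction summed, 15 between Cd163-positive and -negative cells, 2 for the interaction with infection and 293 for class differences. In that order, no low-count filter gave 255, 424, 999, 1664, 3338 and 2410, and 1036 for class differences. DESeq2 gave 43, 107, 82 and 1541, 2227 for the summed CD45-negative fraction, and 1 for Cd163 with the mouse as a block. The replicate block gave 127, 136 and 995 for marginal zone/metallophilic cells, other CD64-positive and CD45-negative classes. For the other CD64-positive classes, RLE gave 21, library totals 73, at least 2000 UMIs 21, Leiden 0.5 19 and ambient subtraction 464, which gave 650 for class differences. For the CD45-negative classes Leiden 0.5 gave 1520, Leiden 2.0 1064 and equal cells 983, and doublets kept gave 555 in the summed fraction. For the Cd163 comparison and its interaction, no thinning gave 127 and 12, at least 2 UMIs 6 and 0, and no block 2 and 0. Leaving out 1 library, the lone sample being assumed to vary like the other group, gave in the order above 87 to 629, 185 to 372, 115 to 2107, 17 to 2787, 1088 to 3933, 0 to 2493, 6 to 22, 0 to 4 and 210 to 1457.

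The Cd163 log2 fold change of −2.67 was −2.59 with the replicate block and −2.63 in DESeq2, both past the threshold (adjusted p = 4.3e-07 and 0.000965, against 0.325), and −3.06 to −2.03 without 1 library, where it passed without either control mouse but not without infected mouse 2 (−2.47, adjusted p = 0.0988) or infected mouse 99 (−2.86, 0.161). Its share difference of −30.2 points was −17.7 at 2500 UMIs. Class shares had 8 calls, 5 with at least 2000 UMIs and 6 to 14 without 1 library. Lists had 148 calls, 0 with an estimated correlation and 6 by fry. Direction turned for the red pulp share (0.20 with lymphoid classes left out), Vcam1 in red pulp cells (−0.027 without control mouse 99; −0.027 to 0.14 over the mice), and in marginal zone/metallophilic cells for Spic (0.063 without control mouse 99, 0.0086 with equal cells; −0.19 to 0.063). In the latter it also turned for Slc40a1 (−0.088 without infected mouse 2; −0.088 to 0.56), Cd5l (−0.043 without control mouse 2; −0.043 to 0.95) and Fcgr1 (−0.35 without infected mouse 2; −0.35 to 1.10). With at least 2 Cd163 UMIs it turned for Hbb-bs (0.11) and for the Cdk8 interaction (−0.048). For all of these the cause was not tested. Replicate numbers do not pair the mice: the correlation of the differences was −0.0629 in red pulp cells. Ambient subtraction was not run for summed fractions, and no model could be fitted with at least 2000 UMIs for CD45-negative cluster 17 or with Leiden 0.5 for classical monocyte-like cells, CD64-positive cluster 14 and CD45-negative neutrophil-like cells.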

Other observations

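The tests and values in this part were all chosen only after the result was seen. The eYFP reporter, which marks the Tnfrsf11a lineage, was seen after thinning in 33.1% and 43.2% of control and 43.5% and 37.1% of infected red pulp macrophage-like cells. In marginal zone/metallophilic macrophage-like cells it was seen in 31.4% and 40.2% of control and 35.6% and 35.2% of infected cells. These shares depend on the depth: in the latter class they were 15.4%, 20.6%, 22.4% and 22.4% when thinned to 2500 UMIs and 60.6%, 80.4%, 81.3% and 78.2% without thinning, and in the red pulp class 16.3%, 25.8%, 24.8% and 21.8%, and 48.7%, 69.5%, 68.9% and 57.7%. T cell-like cells had 5.00%, 5.04%, 4.90% and 4.04%, and B cell-like cells 6.46%, 8.46%, 5.50% and 5.17%.

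Across the fitted classes, 14 genes were called in the same direction in 3 or more. Gm2000 was lower in 7 (log2 fold change −0.66 to −1.13), Phpt1 in 5 (−0.79 to −1.10), Rnaset2a in 5 (−0.55 to −1.18), Rnaset2b in 5 (−0.62 to −1.03), Cdk8 in 4 (−0.56 to −0.97), Mt2 in 4 (−0.44 to −1.22) and Rps27rt in 4 (−0.62 to −1.01). Angpt1 (−0.61 to −0.99), Ccser1 (−0.58 to −0.90) and Hypk (−0.49 to −0.61) were lower in 3. The chaperone partner Dnajb1 was higher in 4 (0.60 to 1.24), and Dnaja1 (0.52 to 1.20), Ighg2c (2.60 to 3.85) and Slpi (0.90 to 2.40) were higher in 3. The classes come from the same mice. With control mouse 2, control mouse 99, infected mouse 2 and infected mouse 99 left out in turn, the numbers of classes were 5, 5, 3 and 7 for Gm2000, 3, 5, 4 and 2 for Phpt1, 5, 4, 3 and 3 for Rnaset2a, 3, 4, 4 and 1 for Rnaset2b, 2, 3, 2 and 3 for Cdk8, 3, 3, 2 and 2 for Mt2 and 1, 3, 2 and 2 for Rps27rt. In the same order they were 1, 2, 0 and 0 for Angpt1, 2, 3, 2 and 3 for Ccser1, 2, 2, 0 and 1 for Hypk, 3, 4, 3 and 1 for Dnajb1, 3, 3, 2 and 0 for Dnaja1, 3, 2, 3 and 3 for Ighg2c and 1, 1, 2 and 2 for Slpi.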
